A study of Bifidobacterium breve UCC2003 and Bifidobacterium breve and Mus musculus with 21 samples.

How the data were processed

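Two-colour Agilent arrays carrying probes for the genes of Bifidobacterium breve UCC2003, a gut bacterium, were examined in 2 designs. In the first, 3 arrays compared RNA from the caeca of mice colonised by UCC2003 with the vector pPKCM7 (Cy5) with RNA from UCC2003 grown in MRS medium (Cy3). The strain label of the caecal channel of replicate 3 reads MUCC2003 and was taken as UCC2003, as in the title of that sample. Per the labels, caeca were taken 25 days after inoculation from groups of 5 mice, and the broth culture was in exponential growth at an optical density of 0.5 with glucose as the carbon source. In the second, 18 arrays each compared genomic DNA of another B. breve strain (Cy5) with genomic DNA of UCC2003 (Cy3), with 1 array per strain. All arrays had the same dye orientation, so a dye effect could not be separated from the comparison. The labels state that cDNA was amplified in triplicate, so the 3 expression arrays may be technical replicates, and their spread does not measure variation between mice.

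Spot values came from Agilent Feature Extraction, version 9.5.1.1 per the file headers and 9.5 in the submitters' processing notes. The scanner files hold signals as intensity on a linear scale per the file headers, both as mean pixel brightness with its local background and as processed signals. The authors' processed signals are background-subtracted, spatially detrended and scaled with 1 dye factor per channel and array. The deposited series values are the log10 ratio of Cy5 over Cy3 processed signals and are not centred on 0. They differed from the ratio in the scanner files by at most 4.77e-08 over 135660 expression values and by at most 5.00e-10 over 194526 genomic DNA values.

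The expression arrays held 43803 experimental spots, 8262 probes and 1892 features, of which 1843 were loci with a Bbr_ tag. Signals were background-corrected in limma 3.58.1 with normexp and an offset of 50. Ratios were normalised by loess within each array, with control spots and spots marked as outliers by the scanner software given no weight. Values were averaged over the spots of a probe and then over the probes of a gene. A feature was tested where a probe stood well above background in either channel on at least 2 arrays, which left 1891 features. The log2 ratio was tested against 0 with limma's moderated test, two-sided, with Benjamini-Hochberg adjustment over all tested features and a false discovery rate of 0.05. Gene lists were tested with limma's camera at a preset correlation of 0.01, and beside it with an estimated correlation and with fry, adjusted over the 9 lists. On simulated data of 1891 genes with the spread of these arrays, 58% of genes with a log2 change of 1 and 92% of those with 2 were recovered, and 2.56% of calls were false.

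The genomic DNA arrays held 10263 experimental spots, 5664 probes and 1888 features, with 3 probes for each locus. Their log2 ratio was taken from the processed signals and centred on the median of each array, using only probes whose UCC2003 channel was well above background. A locus was called low in a strain where the mean over its probes was -2 or below, and shared where it lay above -1 on all 18 arrays. A low ratio means weak hybridisation to the UCC2003 probe, which absent and diverged sequence both give, and genes that UCC2003 lacks cannot be seen. With 1 array per strain no test within a strain was made. On simulated data of 1836 genes, 99.6% of gene and strain values set to -3 were recovered, with 3 false calls. The simulated noise had the spread of the shared loci and no background floor. These rates therefore do not carry over to arrays of weak Cy5 signal, such as PRL4 and PRL5. Loci low in at least 1 strain were compared with the gene lists and with the caecal calls by Fisher's exact test, two-sided. Neighbouring genes tend to be lost together, so the same comparisons were repeated by rotating the calls around the gene order.

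The files name genes by locus tag only, and the reference annotation at hand, of another strain, did not match these tags. The 16 lists defined by words in a product name therefore had 0 members and were left out, together with the planned centring on ribosomal protein genes. Of the 9 lists used, all by locus tag, 3 were fixed before the data were examined (tad pilus, exopolysaccharide locus and sialic acid locus), as were the tests, the thresholds and most of the alternatives. The other 6 were added once the identifiers were known and before any gene value was seen (sortase pilus loci, galactan locus, lacto-N-tetraose locus, lacto-N-biose locus, CRISPR locus and restriction-modification loci). List names rest on general knowledge of the UCC2003 genome and not on the files. The genes to name were every tad member, up to 4 members of each list with the lowest adjusted p, the extremes of each comparison, and the 10 longest runs of variable loci. Because that rule asked for genes with a named product, at most 2 genes that rose and 2 that fell are named outside the lists.

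Median Cy3 signals of the expression arrays were 1424, 1618 and 2095 in replicates 1 to 3, and median Cy5 signals were 731, 506 and 490, beside Cy5 negative controls of 364, 210 and 238. On the genomic DNA arrays the median Cy5 signal ranged from 128 to 23210. The number of arrays limits the precision. Alternatives covered the background correction, the normalisation, the filter on dim probes, the summary over probes, the source of values, the thresholds, the tests and each replicate left out. The planned counting of NCFB2257 and NCTC11815 as 1 strain was not run, because its condition was not met: their arrays were not the most alike of all pairs. Computations used R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6, matplotlib 3.10.9 and the R package data.table, version 1.17.8.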

Results

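On 3 arrays, transcripts from the caecum of mice colonised with B. breve UCC2003 carrying the vector pPKCM7 were compared with transcripts of UCC2003 in MRS broth, a rich laboratory medium. The labels name no vector for the broth culture, so the sides may differ in the vector as well as in the environment. On 18 arrays, the genomic DNA of 18 other B. breve strains was compared with that of UCC2003. The series title speaks of a conserved factor for colonising the host, and the design text of a mutant in tadA, a gene of the tad pilus, so the tad locus was followed through both sets. The log2 ratios of the 3 expression arrays correlated across genes with r = 0.828, 0.861 and 0.869 for the 3 pairs; genes are not independent replicates. The median SD between arrays was 0.35 on the log2 scale, and between the probes of a gene it was 0.62.

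The first question was which genes UCC2003 expressed at another level in the mouse caecum than in broth. All 7 genes of the tad locus, Bbr_0132 to Bbr_0138, were higher in the caecum. This locus encodes a type IVb pilus, a fine surface filament used for tight adherence. The mean log2 ratio over its genes was 1.96, and it was positive in each gene on each of the 3 arrays. Averaged over probes, Bbr_0135 had a log2 ratio of 2.85 ± 0.22 (SE, n = 3, limma adjusted p = 5.08e-07), but its probes differed (SD 1.32), and by the median over probes it was 2.06, below Bbr_0134 (2.20) and Bbr_0137 (2.14). Bbr_0132 had the lowest ratio, 1.34 ± 0.25 (adjusted p = 3.67e-04). The others had log2 ratios of 1.58 (Bbr_0133), 2.24 (Bbr_0134), 1.79 (Bbr_0136), 2.32 (Bbr_0137) and 1.58 (Bbr_0138). All 21 probes of the locus had a ratio above 0, and 7 of 7 genes also passed when adjusted over the list alone.

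**Figure D1:**
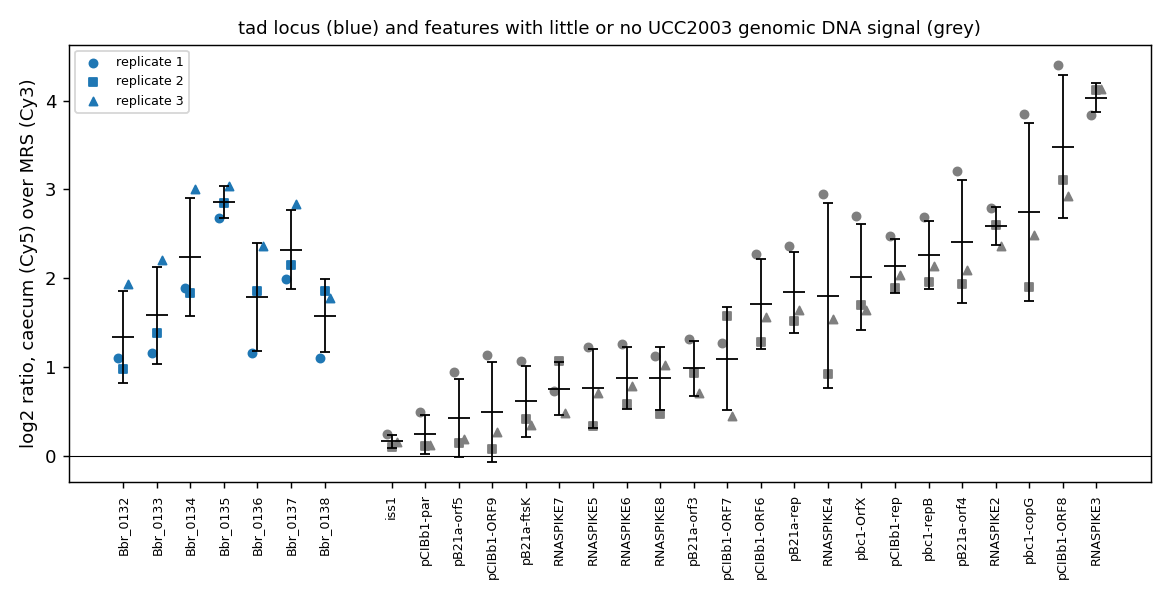
Log2 ratio of caecum over MRS for the 7 tad genes (blue) and for 22 features with little or no signal from UCC2003 genomic DNA (grey), with 1 point per array and bars for the mean and SD over 3 arrays. The tad genes have means from 1.34 to 2.85, and the grey features from 0.16 to 3.99.

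As a set, the tad genes stood above other genes by camera (adjusted p = 0.00157), but not by camera with an estimated correlation (adjusted p = 0.555). That estimate rests on 3 arrays alone, which leaves a list little room to pass, so it decides neither way. By fry, which does not compare a list with other genes, the adjusted p was 0.0350. The 4 restriction-modification genes, Bbr_1118 to Bbr_1121, moved the other way. These enzymes cut foreign DNA or mark the cell's own. All 4 were lower in the caecum, with a median log2 ratio of -1.62, -2.29 in Bbr_1118 (-3.12 with processed signals) and -1.68 in Bbr_1121. Their camera adjusted p was 0.0115, with an adjusted p = 0.555 with an estimated correlation, 0.0350 by fry, and 0.0558 by camera when loess was replaced by median centring. Of the 7 genes of the CRISPR locus, 4 were lower and none higher, among them Bbr_1408 (-1.21) and Bbr_1410 (-1.19), and the list did not pass (median -0.90, camera adjusted p = 0.178).

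Among the 9 genes of the sortase pilus loci, which encode pili assembled by sortase enzymes, 6 were higher and 1 lower, with a median log2 ratio of 0.74. Bbr_0113 had a log2 ratio of 1.37, Bbr_1887 of 1.08 and Bbr_0366 of 0.80. The list did not pass by camera (adjusted p = 0.178) and passed by fry (0.0350), which does not compare a list with other genes. In the sialic acid locus, for uptake and use of a sugar of mucin, 4 of 12 measured genes were higher and 2 lower, also when adjusted over the list alone. The list did not pass (median 0.29, camera adjusted p = 0.237). Under the alternatives its median ranged from 0.02 (median over probes) to 0.47 (processed signals), and it passed by camera under none. Bbr_0160 had a log2 ratio of 2.60. Bbr_0162 had one of 2.65 with an SD of 2.93 between probes, and 1.75 by the median over probes; Bbr_0161 had one of 1.90 with an SD of 2.12 and 2 of its 3 probes above 0. In the exopolysaccharide locus, for the sugar coat of the cell, 4 of 21 measured genes were higher, 2 lower and 15 did not pass. When adjusted over the list alone, 3 were higher and 2 lower. Its median was -0.02, its mean 0.10 and camera's direction down (adjusted p = 0.911), and the median turned positive with median centring, with outlier spots kept, with probes above background in both channels, with the signal of probes without a target subtracted and without replicate 3. Bbr_0433 was highest at 3.15 with an SD of 1.42 between arrays and was at 1.80 with processed signals, and Bbr_0444 was at 1.36 and with processed signals at 2.42. Bbr_0431 was lowest at -1.70, but with processed signals Bbr_0440 (-2.59) lay below it (-2.12).

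In the lacto-N-biose locus, for a building block of mucin and human milk, 3 of 6 genes were lower and none higher, with a median of -0.57 (-1.31 with processed signals, -1.50 with median centring). Bbr_1590 had a log2 ratio of -1.37 (-2.33 with processed signals) and Bbr_1589 of -1.36. In the lacto-N-tetraose locus 2 of 5 genes were lower and none higher, with a median of -0.51 (-0.95 and -1.14). In the galactan locus 3 of 6 genes were higher and 2 lower, among them Bbr_0417 (1.31), Bbr_0422 (1.15) and Bbr_0421 (-0.88). None of these 3 lists passed by camera (adjusted p = 0.178, 0.237 and 0.541), and the lacto-N-biose locus passed by fry (0.0350).

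Across all 1843 loci, 636 were higher and 543 lower in the caecum, and 664 did not pass the limma test. Of the 1179 that passed, 1162 had the same direction on all 3 arrays. Ratios above 5 were found for 53 genes and below 0.2 for 21, a balance that depends on the processing. Processed signals, with another background correction and no loess, gave 98 and 99, and median centring in place of loess gave 45 and 102. With loess normalisation, the largest log2 ratios belonged to Bbr_1070 (4.49 ± 0.24, SE, n = 3, adjusted p = 3.77e-08) and Bbr_0875 (4.25). The lowest belonged to Bbr_0541 (-3.26 ± 0.22, adjusted p = 1.62e-07) and Bbr_1010 (-3.08); with processed signals or median centring other genes were lowest. The files pair these tags with no product names. Changed genes lay side by side: 654 of 1842 neighbouring pairs changed the same way, against a mean of 379 in shuffled orders (highest 433, permutation p = 1e-04, the smallest that 10000 shuffles give). The longest runs were 16 lower genes from Bbr_1007 to Bbr_1023 and, with 12 higher genes each, Bbr_0040 to Bbr_0051 and Bbr_1899 to Bbr_1910.

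Signal in the caecal channel was weak. Of 22 features with little or no signal from UCC2003 genomic DNA (RNA spikes, plasmids of other strains and an insertion element, at most 0.50 above the negative controls on the log2 scale), 18 were also called higher and 0 lower, with a median log2 ratio of 1.40. They are called features without a target here. The one-sample test and limits stated in the design text (ratio above 5 or below 0.2, p under 1e-04) called 0 genes on these ratios in either direction, against 53 and 21 by limma.

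The second question was which UCC2003 genes other strains of the species share. Of the 1836 loci measured on all 18 arrays, 1303 (71.0%) were shared by every strain and 477 (26.0%) were low in at least 1 strain. The tad locus was among the shared ones. None of its 125 measured values was low; the lowest log2 ratio was -0.55, in Bbr_0135 of strain 461, and the median was -0.12. Bbr_0136 was not measurable on the array of NCIMB8815. The sortase pilus loci parted: Bbr_0113 to Bbr_0115 and Bbr_0365 to Bbr_0367 were low in no strain (lowest -0.52 and -0.34), and Bbr_1887 to Bbr_1889 were low in part or in full in 14 strains, all but JCM7017, NCFB2258, NCIMB8815 and 658.

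The exopolysaccharide locus varied between strains. Of its 20 measured genes 19 were low in at least 1 strain, and 75.3% of its values were low. Its odds ratio was 56.3 (Fisher's exact test, adjusted p = 7.90e-10). All strains but PRL5, the array with the dimmest Cy5, had a low gene in it at the threshold of -2; in PRL5 Bbr_0437 (-1.23), Bbr_0439 (-1.68), Bbr_0440 (-1.82) and Bbr_0441 (-1.85), low in the other 17 strains, fell short of it. In 14 strains most of its genes were low. All 7 CRISPR genes were low in at least 1 strain, with low genes in 12 strains (Fisher's exact adjusted p = 3.48e-04), and so were all 4 restriction-modification genes, with low genes in 15 strains (adjusted p = 0.0135). With calls rotated along the gene order these 3 lists had adjusted p = 0.377, 0.451 and 0.451, so a test that respects the grouping of genes did not separate them from other stretches of the genome. No gene was low in the lacto-N-tetraose and lacto-N-biose loci. However, Bbr_0528 of the former followed Bbr_0419 of the galactan locus across arrays (1.17 and 1.20 in PRL4, -0.90 and -0.86 in 12L). Bbr_0527 likewise followed Bbr_0418 (-0.61 and -0.66 in PRL5). On these arrays 9 probe sequences were shared between loci. For these genes the signal of one locus could not be told from that of the other. In the galactan locus Bbr_0422 was low in 5 strains, among them NCFB2257, NCTC11815 and LMG13208, whose arrays were much alike. In the sialic acid locus Bbr_0168 was low in NCIMB8815 alone (-2.14). On the same array Bbr_0160 (-1.98), Bbr_0162 (-1.80) and Bbr_0161 (-1.76) lay close behind, and the low genes of this list numbered 5 at a threshold of -1, 0 at -3, 3 with normexp and 2 with the median over probes.

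**Figure D2:**
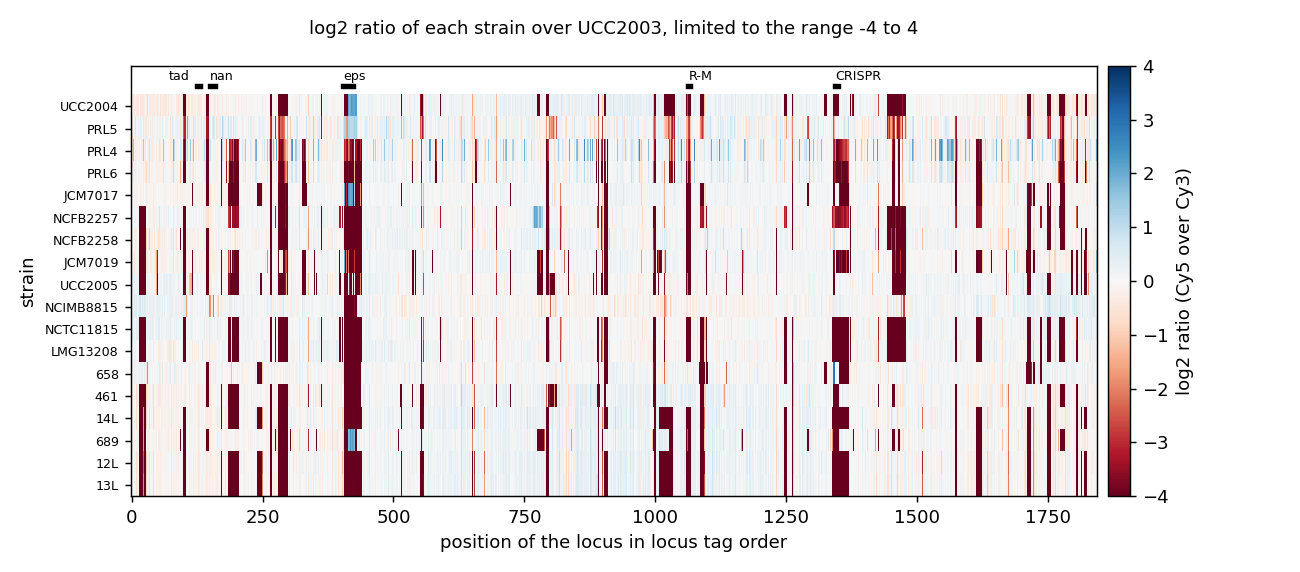
Log2 ratio of each of 18 strains (vertical axis, 1 array each) over UCC2003 at the loci in tag order (horizontal axis), with colour limited to the range -4 to 4 and black bars over the tad, sialic acid (nan), exopolysaccharide (eps), restriction-modification (R-M) and CRISPR loci. Low values form blocks: 284 of the 335 genes low in at least 5 strains lie in 24 runs.

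Variable genes lay in blocks. Runs of at least 5 neighbouring loci, each low in at least 5 strains, numbered 24 and held 284 of the 335 loci that were low in at least 5 strains (84.8%). The 10 longest were Bbr_1508 to Bbr_1548 (36 genes), Bbr_0434 to Bbr_0471 (34 genes, with most of the exopolysaccharide locus), Bbr_0197 to Bbr_0220 (22), Bbr_0299 to Bbr_0321 (20), Bbr_1415 to Bbr_1432 (18), Bbr_0018 to Bbr_0034 (13), Bbr_1400 to Bbr_1411 (12, with the CRISPR genes), Bbr_1689 to Bbr_1699 (11), Bbr_1077 to Bbr_1086 (10) and Bbr_1855 to Bbr_1864 (10). The first run had no low gene in 658, 14L, 12L and 13L. The run Bbr_0299 to Bbr_0321 had low genes in all 18 strains and was mostly low in 16 of them. No locus was low in all 18 strains, 42 were low in at least 15, and 36 in exactly 1.

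Strains differed in how many loci were low. The median was 213 per strain. NCIMB8815 had the fewest, 34, of which 18 lay in the exopolysaccharide locus, and NCTC11815 had the most, 279, just ahead of JCM7019 and LMG13208 (278 each). At a threshold of -1 and with normexp JCM7019 had the most (295 and 283), and at -3 LMG13208 did (273). The arrays of 12L and 13L, on the same slide, were the most alike (r = 0.997 across genes), with 267 of the 271 loci low in either strain low in both. The array of 14L, on another slide, was close to both (r = 0.996 with 12L and 0.995 with 13L) and shared 266 of 267 low loci with 13L. NCTC11815 and LMG13208 shared 276 of 279 low loci, and PRL4 and PRL6 shared 196 of 210. All these arrays count as separate strains here, so a number of strains is not a number of distinct genomes. PRL5 and PRL4 had the weakest Cy5 over background, a median of 1.21 and 1.76 times the negative controls, and their 125 and 197 low loci fell to 7 and 0 with normexp background correction. NCFB2257 and NCFB2258 stood at 3.20 and 3.26 times, and their 276 and 191 low loci fell to 4 and 53.

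**Figure D3:**
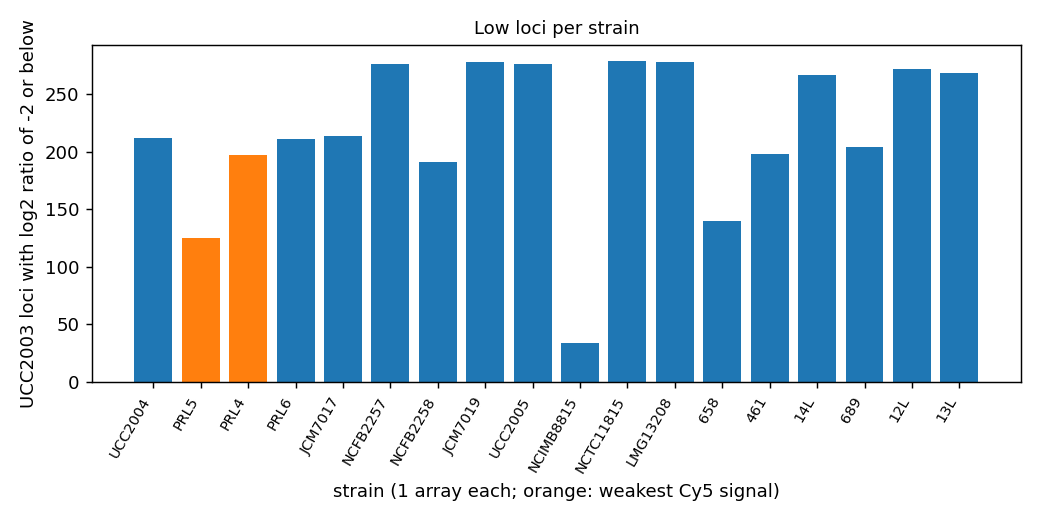
Number of UCC2003 loci with a log2 ratio of -2 or below in each of 18 strains, 1 array per strain, with the 2 arrays of weakest Cy5 over background in orange. Counts run from 34 in NCIMB8815 to 279 in NCTC11815.

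The third question joined both sets: whether the genes that changed in the caecum are those that vary between strains. Of 633 genes higher in the caecum, 240 (37.9%) were low in at least 1 strain, against 19.6% of the other genes (odds ratio 2.51, Fisher's exact adjusted p = 5.84e-17). Of 541 genes lower in the caecum, 61 (11.3%) were low in at least 1 strain, against 32.0% of the others (odds ratio 0.27, adjusted p = 5.04e-22). Rotating the calls along the gene order, a permutation test, gave p = 5.45e-04 in each direction, the smallest that 1834 rotations allow. The tad genes were higher in the caecum and low in no strain, as were most of the higher genes. The restriction-modification genes were lower in the caecum and low in at least 1 strain.

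Both relations depended on the signal in MRS. Compared within 10 groups of genes of like MRS signal, a test chosen after the result was seen, the Cochran-Mantel-Haenszel odds ratio was 0.82 for higher genes (permutation p = 0.172) and 0.88 for lower genes (0.523). The MRS signal is itself part of the caecal ratio.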

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

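The tests on signal without a target, GC content, neighbouring loci, weak MRS signal and DNA shared between arrays of a slide were chosen only after the results were seen, and the sign patterns were planned.

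Of 22 features with little or no signal from UCC2003 genomic DNA, 18 were called higher in the caecum, a signal in data outside the comparison of loci. The ratios of the tad locus, 1.34 to 2.85, lie inside the range of those features, 0.16 to 3.99 (RNASPIKE3, with the next at 3.48). RNA spikes may have been added during labelling, and the caecal strain carried the vector pPKCM7, whose sequence the files do not give. Without the spikes and the pbc1 plasmid features 8 of 12 were still higher. In all, 8.81% of the higher genes, 9.52% of the tad probes and 0 tad genes lay above the 95th percentile of those probes on all arrays, against 5.70% of all loci. Above their median lay 99.8% of the higher genes and all 21 tad probes, against 97.2% of all loci. The percentile was at first read as counting against the higher calls, a reading set aside after its outcome was seen.

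Stray signal at the median level of those features is argued against as the source of the calls. Once it was subtracted, 618 of the 636 higher genes (97.2%) and 7 of 7 tad genes still passed. That level lay below 97.2% of all loci, and loess was refitted after the subtraction, so stray signal of a higher level was not tested. GC content is argued against for the tad locus only. Its genes lay at 48.3 to 53.9% GC, near the median of 51.1%, and 7 of 7 passed with the trend removed. Over all loci that removal left 582 higher and 589 lower genes, with 39 ratios above 5 against 53 before. Of the 636 higher genes 576 still passed. Signal set by probe sequence alone is argued against by the correlation that neighbouring genes kept after MRS signal and GC content (r = 0.349, permutation p = 0.0001, the smallest possible). Stray signal specific to a probe and transcript cannot be told apart for single genes or the tad locus: the comparisons of Cy5 levels (8.81% above, and 1.15 more log2 signal on tad genes, one-sided permutation p = 7e-05) set different probes side by side and decide nothing. For the tad locus weak signal in MRS stays open too, as 5.23% of windows of 7 loci were as high after the trend on MRS signal and GC content. With the sign of any 1 array turned 0 genes passed against the real 1179, so 1 of 4 sign patterns gave as many, and 4 are too few for a share under 0.05; a response to the mouse gut, the vector, transcripts of other caecal bacteria and amplification of the cDNA stay open and were not tested.

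The probes of pCIBb1, a plasmid with little signal from UCC2003 DNA, gave a median Cy5 signal of 12.8 times the negative controls on the array of NCFB2258 and 1.93 times on that of NCFB2257, where every one of its 6 features lay above all RNA spikes. The arrays shared a slide. Without passing the spikes the median was higher still than on NCFB2257 on the arrays of JCM7019 (3.25), UCC2004 (2.28) and JCM7017 (2.11), so this signal alone does not set NCFB2257 apart. Among genes low in both NCTC11815 and LMG13208, which resemble NCFB2257, the 101 present in NCFB2258 had a median log2 ratio of -3.33 on the array of NCFB2257 and the 171 low in NCFB2258 one of -5.10, a difference that exceeded those on the arrays of NCTC11815 and LMG13208 by 1.49 (two-sided permutation p = 1e-05, the smallest possible). A candidate explanation is that some DNA of NCFB2258 reached the array of NCFB2257; 98 of the 101 genes were still called low, so the calls changed little. That NCFB2257 carries a related plasmid was not tested.

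The feature iss1 gave a median Cy5 signal of 1.92 times the negative controls on the array of LMG13208, just above every RNA spike on that array (1.87); on that of UCC2004 it gave 4.20 times, below the highest spike (11.7).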

How the results depend on the processing

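The filter and the subtraction that use probes without a target, and the comparison within groups of like MRS signal, were chosen after the results were seen. Of 349 values under alternatives, 323 were counted as the same. Counts and means had to stay near the reported value, and lists had to stay on their side of the threshold. A change of sign was looked for only in lists that passed, so the exopolysaccharide medians that turned positive are among the 323. Of 189 list values 186 were counted as the same, most of them from lists that passed in neither setting. With processed signals the genes with a ratio above 5 numbered 98 and below 0.2 numbered 99, and with the series values 97 and 99; the tad mean was 2.49 with both. Median centring gave 102 genes below 0.2 and 1 list past the threshold, and subtracting the median signal of probes without a target gave 50 genes below 0.2. The one-sample t-test gave 0 and 0 genes at the stated limits, whose p it can hardly reach with 3 arrays. After Benjamini-Hochberg it gave 22 higher, 20 lower, 4 above 5 and 3 below 0.2, and it uses no spread pooled over genes. Requiring signal above the 95th percentile of probes without a target left 56 higher genes, 24 above 5 and 0 tad genes. Camera with an estimated correlation, which 3 arrays leave little room to pass, left 0 lists past the threshold, and fry gave 4. The median over probes moved the median of all genes by -0.15 and gave 492 higher and 588 lower genes. Rotation along the gene order left 0 lists among variable genes. Within groups of like MRS signal the odds ratio was 0.82 for higher and 0.88 for lower genes. Apart from these tests and filters, whose construction sets the counts, the cause was not tested. Leaving out 1 replicate gave 496 to 565 higher and 434 to 455 lower genes, 55 to 59 above 5, 20 to 28 below 0.2, 7 tad genes with a mean of 1.71 to 2.15, and 2 lists. The genes low in at least 1 strain numbered 462 to 533, and the tad locus had 0 low values under every alternative run. With normexp, PRL4, NCFB2257 and PRL5 had only 0, 4 and 7 low loci in all, so on these arrays that setting could hardly show a loss. Signal over background limits both sets, among others in PRL4, PRL5 and the caecal channel. The ribosomal centring could not be run, since no gene was named.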

Other observations

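The tests on the UCC2003 signal of the exopolysaccharide locus were chosen only after the pattern was seen; those on the type strain and on shared slides were planned.

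In some strains a run of exopolysaccharide genes gave more signal than in UCC2003. The genes Bbr_0442 to Bbr_0454 had a median log2 ratio of 2.14 in UCC2004 and 2.12 in 689, and Bbr_0442 to Bbr_0451 one of 2.08 in JCM7017, all on arrays where the UCC2003 signal of the locus was itself low. In PRL5, Bbr_0442 to Bbr_0452 had a median of 1.08. There the UCC2003 signal of the locus lay between those arrays and most others (-0.40 from the array median, beside 0.03 in UCC2005). UCC2005 kept 4 of these genes without such a rise, Bbr_0442 (0.38), Bbr_0443 (-0.02), Bbr_0449 (-0.58) and Bbr_0450 (-0.36). On the array of 689 these 13 genes were all of the genes above 1. NCFB2257 had another such block, the 19 genes from Bbr_0811 to Bbr_0829, with a median of 1.78 (SD 0.34 over genes), which were again all of its genes above 1; the other strains had medians of at most 0.34 there. PRL4, a dim array with 197 genes above 1, had 3 shorter runs, Bbr_1615 to Bbr_1619 (2.10), Bbr_1629 to Bbr_1634 (1.71) and Bbr_1636 to Bbr_1642 (2.18). The feature tRNA-Tyr was low in 14 strains. On the expression arrays tRNA-Asp (2.59) and tRNA-Val (2.58) had high log2 ratios and tRNA-Glu (-2.56) a low one; these blocks and features were singled out after their values were seen.

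The UCC2003 channel itself differed at this locus. On 8 arrays (UCC2004, JCM7017, JCM7019, 461, 14L, 689, 12L and 13L) the Cy3 signal of its 20 genes lay -1.54 to -1.17 from the array median on the log2 scale, and on the other 10 arrays -0.41 to 0.33. On each of those 8 arrays the locus was lower, relative to the median of each gene over all arrays, than all 1745 other windows of as many loci. On 7 of the other 10 it was higher than all of them. The remaining arrays, PRL4, PRL5 and PRL6, stood between (-0.41, -0.40 and -0.38 from the array median). The locus lay above the lowest of the 100 windows nearest in GC content on 0 of those 8 arrays. On them the lowest such window stood at -0.29 by this measure, and the locus at -0.72 or below. This argues against a GC effect shared with those windows. All of them, at 45.4 to 46.9% GC, were richer in GC than the locus (44.4%), so an effect confined to lower GC content was not tested. Competition of the other strain's DNA for the same probes would need a strain that has the locus, but 5 of the 8 strains were low in most of its genes. A candidate explanation is less of the locus in the UCC2003 DNA of some arrays, or more on the others; both arrays of a slide were alike on 7 of 7 slides, and no growth or DNA batch is given in the labels to test this further.

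The hypothesis that NCFB2257 and NCTC11815, both collection numbers of the type strain, hold the same genome was tested by rank: their arrays correlated with r = 0.963, rank 6 among all pairs, and shared 274 of the 279 loci low in either. The rank leaves it open. The pairs of LMG13208 with NCTC11815 (r = 0.989) and with NCFB2257 (r = 0.965) ranked above it, but LMG13208 may be a further number of the same strain, which the labels do not say, so its pairs do not speak against one genome; the array of NCFB2257 may also carry other DNA (excess 1.49 above). Hybridisation of both arrays on 1 slide as a general source of shared calls stays open. No general rise was seen: the 7 pairs on a slide had a median r of 0.491 and other pairs 0.555 (one-sided permutation p = 0.875). Correlations ran from -0.115 to 0.997 with the strains compared, so 7 pairs could not show a smaller effect.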
